A study of Rattus norvegicus with 12 samples.

How the data were processed

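Total RNA was prepared from the 12 cultures with the RNeasy kit and turned into sequencing libraries with the Ovation RNA-seq System v2 kit, per the labels' protocols. The deposited table holds whole-number read counts per gene that the authors did not normalize, with 32545 genes identified by Ensembl rat gene numbers, symbols and positions. The submitters' processing notes name the aligner Bowtie 0.12.2 and the genome builds mm8 and Rnor_6.0, without roles. The rat gene positions in the table fit Rnor_6.0, and positions are given in that build. The counting program, the annotation release, and the use of strand are not given in the sources used here. Reads of overlapping or antisense genes, of near-identical family members, and of the viral and endogenous copies of Sall4 and Gata4 therefore cannot be separated. Bowtie in this version does not align across introns, per general knowledge of the program, and how the authors treated reads that span exon junctions is not given.

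Groups came from the sample labels, and the design text states that each group holds biological replicates. Within each group, pairs of libraries differed by 4.44 to 7.57 times the chi-square expected from sampling noise alone per degree of freedom, over genes with at least 50 counts, in all 12 pairs, so none looks like a second sequencing of the same library. That the RNA came from separate biological replicates rests on the design text. Log2 profiles of replicates correlated at 0.984 to 0.988 across genes, which are not independent replicates.

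Counts were scaled with TMM factors and fitted in edgeR 4.0.16 under R 4.3.3, with limma 3.58.1. Genes were kept by filterByExpr, which left 14399 tested and 18146 untested. One quasi-likelihood model with a term per group was fitted over all 12 libraries, with robust dispersion (biological coefficient of variation 9.72%, 8 residual degrees of freedom, median prior 20.6). Each comparison was a two-sided contrast, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Main comparisons were GS with RCF, GS_diff1 with GS, GS_diff2 with GS and GS_diff2 with GS_diff1, and both differentiated groups with RCF were secondary. A gene with 0 counts in all libraries of a group is given as at least N-fold, against a floor of 3 counts per library, which covers counting error only. Where a group held only a few counts, the report gives levels without a fold. The balance of higher and lower genes moves with the scaling, and the report gives it also with library totals alone where it moved most.

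The 20 gene lists, the tests, the alternatives and the rule for named genes were set before the data were examined. The lists cover fibroblast and extracellular matrix, contractile smooth muscle and myofibroblast, cardiomyocyte, cardiac mesoderm and progenitor, pluripotency, endothelial, epithelial and mesothelial, endoderm and hepatocyte, neural and glial, leukocyte, and pericyte genes. They also cover cell cycle, growth arrest genes and cell cycle inhibitors (such as Cdkn1c, Sesn2 and Gadd45a), interferon response, cholesterol synthesis, glycolysis and hypoxia, fatty acid oxidation and oxidative metabolism, unfolded protein and amino acid stress, immediate early, and Wnt, Notch and BMP target genes. The list named growth arrest genes and cell cycle inhibitors also holds cell death and stress genes, such as Bax, Fas and Perp. Its counts and p-values therefore cover more than growth arrest. Of 520 listed symbols, 502 matched a gene in the table, 5 of them through other names in a RefSeq table of the GRCr8 assembly, which was used for names only, and 413 list memberships were tested. Members that did not pass the filter were left out. Tested were, for example, 17 of 31 pluripotency, 8 of 22 endoderm, 19 of 32 endothelial and 23 of 37 cardiomyocyte genes. A member at 0 in RCF enters only through its counts in other groups, which favours higher calls in GS against RCF. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 20 lists of a comparison, and again with an estimated correlation. Camera compares a list with the other genes, while fry asks whether a list's genes move on balance one way. Calls lost with an estimated correlation are given with that adjusted p, and every other camera call in the 4 main comparisons held. Those that held had larger adjusted p-values with an estimated correlation. For cell cycle genes in GS_diff1 against GS, camera's value went from 9.14e-30 to 0.000209. It went from 0.000814 to 0.0486 for contractile genes in GS_diff2 against GS, and from 0.000635 to 0.0428 for immediate early genes in GS against RCF.

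The rule for named genes took Sall4, Gata4, Tert, Cdkn2a and Rb1, among others. It added, in each main comparison, the 6 largest rises and 6 largest falls among called genes with non-overlapping libraries and at least 10 CPM in the higher group. It also added, with at least 1 CPM, up to 3 called members with the largest change in the majority direction of the fibroblast, cardiomyocyte, pluripotency and endothelial lists. The same was done for each other list with a camera adjusted p under 0.05 or at least 50% of tested members called. It gave 184 genes, of which the text describes a part, and some are not reported here. Cd68, Esm1 and other listed genes may appear with levels in comparisons beyond the one that named them. In GS against RCF, Wt1, Aldh1a2, Lrrn4 and Dcn were chosen after their values were seen.

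The tests were run on simulated counts made from the GS and RCF libraries, with 14399 genes and 50 changed genes for each fold. The edgeR test recovered 36% of genes changed 1.2-fold, 56% at 1.5-fold, 62% at 2-fold and 76% at 4-fold, with 9 false calls and 0 calls of the wrong sign. Among changed genes with a mean of at least 100 counts, a division chosen after the first values were seen, it recovered 47.4%, 84.4%, 91.2% and 97.2%. DESeq2 made 17 false calls and limma-voom 6. Camera called 0 of 20 random lists and called the list that had been changed. The simulated genes varied independently of one another, so these lists do not test the preset correlation. Recovery rose with the fold and the count, so at 16255682 to 23117864 counts per library low counts limit what can be detected.

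The alternatives were DESeq2 size factors, library totals without composition factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter at a mean of 1 CPM, a fit on the libraries of both compared groups alone, the replicate number as a block, and leaving out each library in turn. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Isoforms, allele-specific expression and the viral sequences were not analysed here.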

Results

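RNA was sequenced from rat cardiac fibroblasts, the matrix-producing stromal cells of the heart, and from cells derived from them with viral Sall4 and Gata4. Sall4 is a zinc finger transcription factor of early embryonic and germ cells, and Gata4 is a zinc finger transcription factor of heart and endoderm development. The 12 libraries fell into 4 groups with 3 biological replicates each. RCF are the untreated parental fibroblasts that served as controls. GS are the immortalized, undifferentiated cells that carry both factors. GS_diff1 are GS cells placed in CMM medium, which the labels tie to cardiomyocyte differentiation. GS_diff2 are GS cells placed in CMM medium with EGM2 solution, which the labels tie to cardiomyocyte and endothelial differentiation. Libraries held 16255682 to 23117864 counts, and 16044 to 16707 genes had at least 1 count in a library. The first principal component of log2 normalised counts (CPM, counts scaled to a common library size) held 58.0% of the variance and put the RCF libraries apart from all others. The next components, with 19.5% and 12.5% of the variance, separated GS, GS_diff1 and GS_diff2 from one another. All levels are mean normalised read counts in CPM, with ± SD where given and n = 3 libraries per group. A ± after a log2 fold change is its standard error, worked out from the F statistic of the test. Adjusted p-values are from edgeR's quasi-likelihood test for genes and from camera for gene lists.

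Sall4 and Gata4 were examined first because they define the GS cells. Sall4 (ENSRNOG00000050035, Rnor_6.0 chromosome 3, 165520392 to 165537940, minus strand) had 0 counts in each RCF library and 3689 to 5363 counts in the GS libraries. Its level was 246 ± 8.58 CPM in GS, 225 ± 4.67 in GS_diff1 and 69.6 ± 2.55 in GS_diff2. Against a floor of 3 counts per library, GS was at least 1750-fold higher than RCF (adjusted p = 1.9e-34). Gata4 (ENSRNOG00000010708, chromosome 15, 46386712 to 46432965, minus strand) was already present in RCF at 206 ± 3.43 CPM. It was 595 ± 7.21 CPM in GS, 2.89-fold higher (log2 1.53 ± 0.0289, adjusted p = 5.02e-28), then 495 ± 6.97 in GS_diff1 and 285 ± 3.89 in GS_diff2. In GS_diff2, Sall4 was 3.54-fold and Gata4 2.09-fold lower than in GS (adjusted p = 1.41e-24 and 5.71e-24). In GS_diff1, Gata4 was 1.202-fold lower than in GS (adjusted p = 1.4e-09). Sall4 was 1.09-fold lower there (log2 -0.13 ± 0.0384, adjusted p = 0.00521), a call that ended with library totals as the only scaling (log2 -0.07) and without GS replicate 2 (log2 -0.09). Reads from the viral copies and from the rat genes cannot be separated in these counts.

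**Figure D1:**
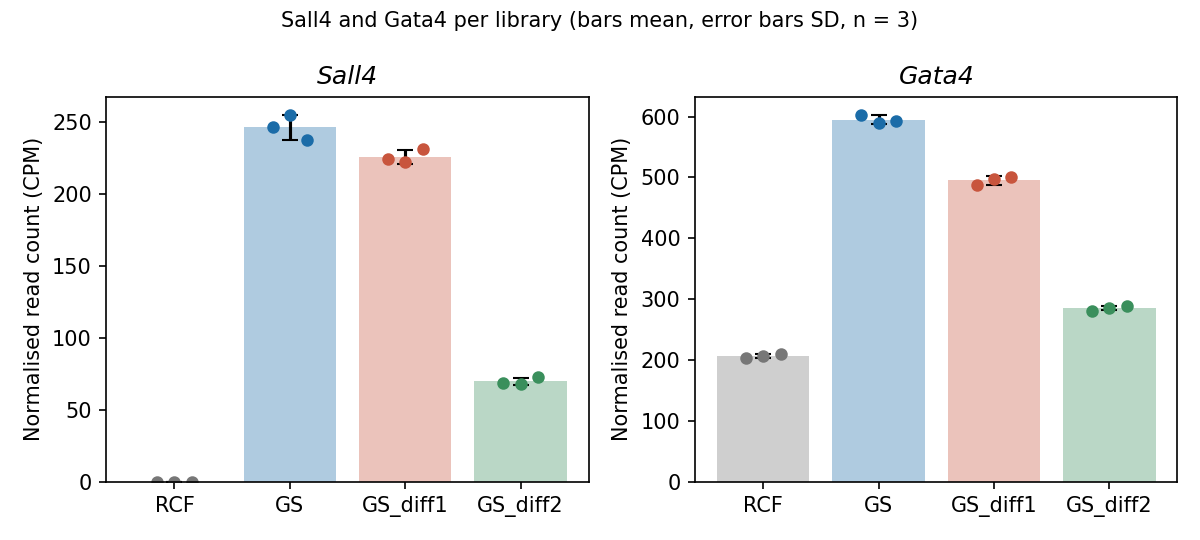
Normalised read counts (CPM, vertical axis) of Sall4 and Gata4 in each of the 12 libraries (points), with the mean of each group as a bar and the SD as an error bar (n = 3). Sall4 was at 0 in the RCF libraries, and both genes were highest in GS and lower in GS_diff2 (69.6 and 285 CPM) than in GS_diff1.

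Genes tied to immortalization and growth arrest were read in every group. Tert, the catalytic subunit of telomerase, was at 2.44 ± 0.231 CPM in RCF and 3.42 ± 0.91 in GS (adjusted p = 0.0809), a difference that passed the test without GS replicate 2 (log2 0.69). It was 2.92 ± 0.736 CPM in GS_diff1 and 4.85 ± 0.399 in GS_diff2, 1.66-fold apart (adjusted p = 0.0106), and that call ended without GS_diff1 replicate 2 (log2 0.53). Tert in GS_diff2 against GS missed the threshold (adjusted p = 0.0729) and passed it with library totals only (log2 0.58), limma-voom (log2 0.51), only the libraries of both groups (log2 0.50) and without GS replicate 1 (log2 0.69). Rb1 was 1.27-fold lower in GS than in RCF (adjusted p = 0.00074). Cdkn2a, which encodes a cell cycle inhibitor lost in many immortal cells, remained detectable at 11 ± 4.01 CPM in GS against 7.81 ± 0.96 in RCF (adjusted p = 0.21). It was 45.7 ± 13.7 CPM in GS_diff2, 4.18-fold higher than in GS (adjusted p = 0.000261).

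The comparison of GS with RCF addresses what set the immortalized Sall4 and Gata4 cells apart from their parental fibroblasts. Several genes of early embryonic, endoderm and epithelial cells had 0 counts in RCF and were abundant in GS. Sox17, an endoderm and endothelial transcription factor (ENSRNOG00000027357, chromosome 5, 14890408 to 14895907), reached 710 ± 12.9 CPM, at least 5040-fold above the RCF floor. Lin28a, an RNA-binding protein of pluripotent cells (ENSRNOG00000060320, chromosome 5, 152230343 to 152247332), reached 170 ± 5.8 CPM, at least 1200-fold above it. Krt18, a keratin of simple epithelia (ENSRNOG00000047393, chromosome 7, 143629455 to 143633131), reached 161 ± 3.49 CPM, and the tight junction gene Cldn6 reached 79.3 ± 3.67 CPM. In the other direction, complement component C7 fell from 53.8 ± 1.47 CPM to 0, at least 320-fold, and Adgre1, a macrophage surface receptor, fell from 14.3 ± 0.981 CPM to 0, at least 85.3-fold. Spon1, a matrix protein gene, was at 0.585 ± 0.0101 CPM in GS against 143 ± 5.33 in RCF, and Star, a cholesterol transport protein of steroid-producing cells, was at 0.313 ± 0.233 against 69.4 ± 3.75. In all, 10262 of 14399 tested genes differed, 5039 higher and 5223 lower in GS, and 3733 of them by at least 2-fold. With library totals as the only scaling, 4383 were higher and 6024 lower. RT1-CE16, also absent from RCF and at 77.8 ± 2.36 CPM in GS, belongs to the MHC class I family, whose members share sequence, so its value is uncertain.

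Tested genes of pluripotent and progenitor cells were more often higher than lower in GS. Of 31 pluripotency genes in the table, 17 had enough counts to be tested. Of these, 14 were higher, 2 lower and 1 not called (camera adjusted p = 4.92e-08). Members at 0 in RCF, such as Lin28a and Tdh, passed the filter only through counts in other groups. That favours higher calls here and in the other lists, and the p-value makes no allowance for it. Besides Lin28a, Sall1 was at 109 ± 8.4 CPM against 0.0141 ± 0.0244 in RCF, and Tdh was at 3.85 ± 0.99 CPM against 0. In the cardiac mesoderm and progenitor list, 15 of 22 tested genes were higher and 3 lower (camera adjusted p = 0.00115). Fgf10, a growth factor of the second heart field, was 77.1-fold higher at 77.2 ± 2.41 CPM. The transcription factor Hand1 was at 12.4 ± 0.704 CPM against 0.0316 ± 0.0546, and Nkx2-5, an early cardiac transcription factor, was at 3.38 ± 0.402 CPM against 0. Of 23 tested cardiomyocyte genes, 12 were higher and 6 lower (camera adjusted p = 0.0896), and the list did not stand apart from other genes. Its members included the sarcomere genes Myl3, at 53.6 ± 2.97 CPM against 0.0158 ± 0.0273, and Mybpc3, at 16.1 ± 3.22 CPM against 0.

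Genes of other lineages moved as well. Of 24 tested epithelial and mesothelial genes, 14 were higher and 9 lower (camera adjusted p = 0.000488), with Esrp1, a splicing regulator of epithelia, at 67.6 ± 2.19 CPM from 0. Among its mesothelial genes, Wt1 fell from 37.2 ± 0.952 to 7 ± 1.15 CPM, Aldh1a2 from 49.4 ± 2.63 to 1.62 ± 0.705, and Lrrn4 from 16.2 ± 1.07 to 4.56 ± 0.811. Of 8 tested endoderm and hepatocyte genes, 6 were higher and 0 lower (camera adjusted p = 0.000879), with Sox17 among them. Endothelial genes were 8 higher and 5 lower of 19 tested (camera adjusted p = 0.0714), with Sox17 and Sox7 among the higher ones. Sox7 was at 66.3 ± 3.68 CPM in GS and 0.113 ± 0.119 in RCF. Neural and glial genes (6 higher, 3 lower of 11 tested, camera adjusted p = 0.444) and pericyte genes (6 higher, 2 lower of 8, camera adjusted p = 0.0657) did not pass as lists, although the pericyte proteoglycan gene Cspg4 was 5.90-fold higher. Leukocyte genes were 1 higher and 11 lower of 13 tested (camera adjusted p = 0.00189, and adjusted p = 0.0599 with an estimated correlation). Cd68, of macrophage lysosomes, was at 14.4 ± 1.73 CPM in RCF and 0.784 ± 0.291 in GS.

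Matrix genes rose more often than they fell. Of 31 tested fibroblast and extracellular matrix genes, 19 were higher and 9 lower in GS (camera adjusted p = 2.18e-05). The metalloproteinase inhibitor Timp3 was 21.3-fold higher at 704 ± 9.44 CPM, elastin (Eln) 14.1-fold and lumican (Lum) 10.3-fold. Decorin (Dcn), a proteoglycan of the same list, fell from 32.8 ± 1.55 to 1 ± 0.533 CPM. Contractile smooth muscle and myofibroblast genes were 8 higher and 10 lower of 19 tested (camera adjusted p = 0.576). Myosin light chain kinase (Mylk) was 3.61-fold and Myl9 2.84-fold lower. Adjusted over the list alone, 29 matrix genes and 19 contractile genes were called instead of 28 and 18, and the counts of the other 18 lists were equal under both adjustments.

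Cholesterol synthesis genes were lower in GS, 22 of 24 tested with 0 higher (camera adjusted p = 1.25e-15). The isoprenoid enzyme Idi1 was 5.98-fold lower, at 6.805 ± 0.602 CPM against 40.93 ± 0.409. Fatty acid oxidation and oxidative metabolism genes were 3 higher and 19 lower of 30 tested (camera adjusted p = 0.00325, and adjusted p = 0.124 with an estimated correlation). Among them, lipoprotein lipase (Lpl) was 10.8-fold and Cpt1a, which admits fatty acids into mitochondria, 2.82-fold lower. The share of counts on mitochondrial DNA genes was 2.21 ± 0.0394% in RCF, 0.244 ± 0.00216% in GS, 1.59 ± 0.104% in GS_diff1 and 1.83 ± 0.0344% in GS_diff2. Glycolysis and hypoxia genes were 5 higher and 14 lower of 25 (camera adjusted p = 0.422). Car9 was at 30.6 ± 3.15 CPM against 2.89 ± 0.519 in RCF, and Egln3 at 114 ± 3.17 against 11.3 ± 0.681. Bnip3 was 1.83-fold and Gapdh 1.72-fold lower. Interferon response genes were 4 higher and 14 lower of 26 (camera adjusted p = 0.0896), with the antiviral GTPase gene Mx1 6.66-fold lower.

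Stress, immediate early and growth arrest genes were more often higher than lower in GS. Unfolded protein and amino acid stress genes were 14 higher and 5 lower of 20 (camera adjusted p = 1.48e-05), and immediate early genes were 13 higher and 6 lower of 21 (camera adjusted p = 0.000635). The stress transcription factor Atf3, a member of both lists, was 47.4-fold higher at 205 ± 2.24 CPM, and Chac1, which degrades glutathione, was 6.49-fold higher. Of 21 tested members of the growth arrest and cell cycle inhibitor list, which also holds cell death genes, 13 were higher and 4 lower (camera adjusted p = 0.000292). Cdkn1c, an imprinted cell cycle inhibitor (ENSRNOG00000059500, chromosome 1, 216661080 to 216663721), was at 214 ± 10.9 CPM in GS and 0.047 ± 0.00455 in RCF. Cell cycle genes were 20 higher and 11 lower of 37 (camera adjusted p = 0.176), with the replication helicase gene Mcm7 2.77-fold higher. Wnt, Notch and BMP target genes were 8 higher and 6 lower of 14 (camera adjusted p = 0.929). For the contractile list, camera and the median pointed down while fry pointed up. For the glycolysis list, camera and the median pointed down while the mean and fry pointed up.

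**Figure D2:**
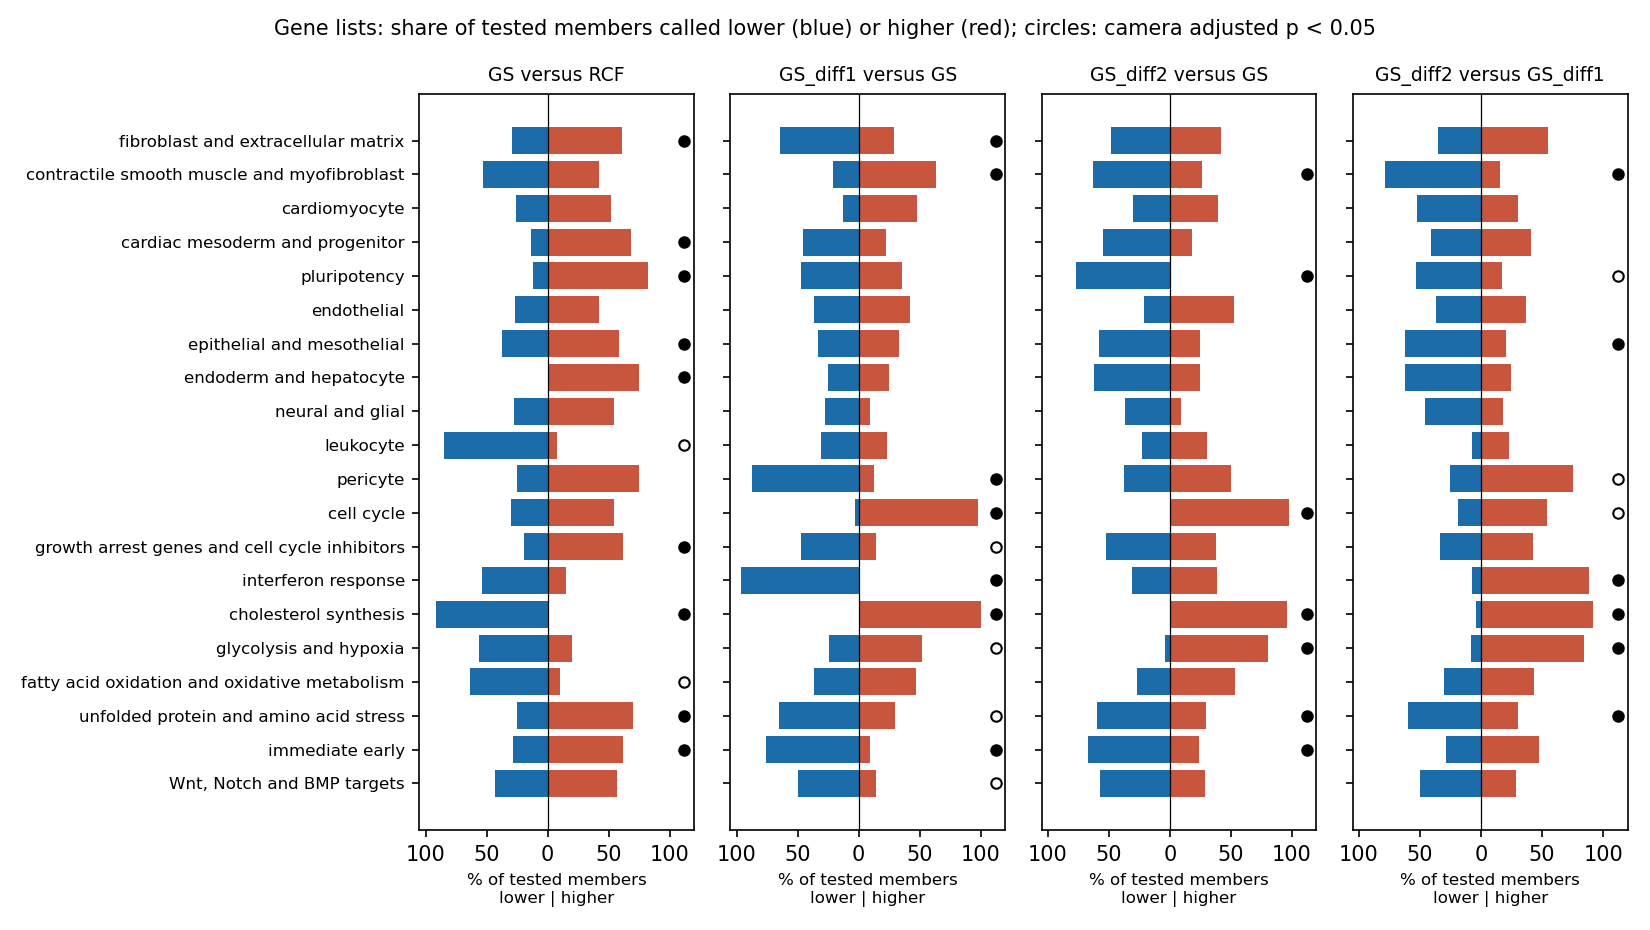
Share of the tested members of each of the 20 gene lists called lower (blue, to the left) or higher (red, to the right) in each of the 4 main comparisons, in percent. A filled circle marks a list with a camera adjusted p under 0.05 that held with an estimated correlation, and an open circle one that was lost with it. Cell cycle genes were higher in 36 of 37 tested members in both differentiated groups against GS.

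GS_diff1 was compared with GS to see what differed in cells placed in CMM medium. The sample titles name no GS cultures matched for time or density. Effects of the medium therefore cannot be told apart from those of culture time or growth state, here and for GS_diff2. Cell cycle and cholesterol synthesis genes mostly rose, and interferon and immediate early genes mostly fell. Contractile genes were mostly higher, and fibroblast and matrix genes mostly lower. Il1rl1, the receptor of interleukin 33 (ENSRNOG00000014835, chromosome 9, 47134034 to 47182170), was 27.0-fold higher, from 3.45 ± 0.282 to 93.8 ± 1.15 CPM. The hepatocyte and endoderm factor Hnf4a was 14.2-fold higher at 26.1 ± 0.575 CPM, and Car3, a carbonic anhydrase, was 11.9-fold higher at 29.9 ± 1.7 CPM. The Wnt modulator Sfrp2 (ENSRNOG00000009465, chromosome 2, 182723854 to 182731764) was 41.8-fold lower, from 457 ± 11.7 to 10.9 ± 0.69 CPM. The growth factor Fgf7 fell from 24.6 ± 1.02 to 0.639 ± 0.298 CPM, and Abcc9, a subunit of ATP-sensitive potassium channels, from 19.3 ± 2.92 to 0.604 ± 0.287 CPM. Mir675 (ENSRNOG00000040350, chromosome 1, 215745981 to 215746064), the microRNA gene that lies inside the imprinted H19 transcript, was 14.8-fold higher at 565 ± 44.7 CPM. Its reads can come from the host transcript. In all, 9256 of 14399 genes differed, 4603 higher and 4653 lower, and 2616 of them by at least 2-fold. With library totals only, 5100 were higher and 4165 lower.

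Of 37 tested cell cycle genes, 36 were higher in GS_diff1 and 1 lower (camera adjusted p = 9.14e-30). Thymidine kinase (Tk1) was 5.39-fold higher, the survivin gene Birc5 4.56-fold and the mitotic kinase Aurkb 4.32-fold. All 24 cholesterol synthesis genes were higher (camera adjusted p = 3.46e-20), with Idi1 11.4-fold. Glycolysis and hypoxia genes were 13 higher and 6 lower of 25 (camera adjusted p = 0.0399, and adjusted p = 0.151 with an estimated correlation), and lactate dehydrogenase (Ldha) was 1.82-fold higher. Fatty acid oxidation and oxidative metabolism genes were 14 higher and 11 lower of 30 (camera adjusted p = 0.677). The mitochondrial gene Mt-nd4l was 12.7-fold higher, from 13.2 ± 0.801 to 167 ± 18.9 CPM, alongside the higher mitochondrial share of counts given above.

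Contractile smooth muscle and myofibroblast genes were 12 higher and 4 lower of 19 in GS_diff1 (camera adjusted p = 0.000283). Smooth muscle actin, Acta2 (ENSRNOG00000058039, chromosome 1, 252537615 to 252550394), was 10.9-fold higher at 961 ± 13.7 CPM, Tagln 3.53-fold and tropomyosin 1 (Tpm1) 2.99-fold. Cardiomyocyte genes were 11 higher and 3 lower of 23 (camera adjusted p = 0.0772). Mybpc3 was 5.90-fold higher at 95.6 ± 3.11 CPM, and the slow skeletal and fetal cardiac troponin gene Tnni1 was at 8.81 ± 1.12 CPM against 0.536 ± 0.133 in GS. Hcn4 of the same list went the other way, from 9.61 ± 0.314 CPM in GS to 0.666 ± 0.0752 in GS_diff1. Adjusted over the list alone, 13 cardiomyocyte genes were called instead of 14, and the counts of the other 19 lists were equal. Fibroblast and extracellular matrix genes were 9 higher and 20 lower of 31 (camera adjusted p = 0.00075), with matrix Gla protein (Mgp) 14.99-fold and Lum 7.33-fold lower. Pericyte genes were 1 higher and 7 lower of 8 (camera adjusted p = 0.000135), with the potassium channel gene Kcnj8 at 0.158 ± 0.095 CPM against 1.86 ± 0.297.

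Interferon response genes were 0 higher and 25 lower of 26 in GS_diff1 (camera adjusted p = 1.96e-07), with Ifit3 7.03-fold and Oasl 4.40-fold lower. Immediate early genes were 2 higher and 16 lower of 21 (camera adjusted p = 2.45e-09), with Egr2 11.7-fold and Egr1 6.41-fold lower. Unfolded protein and amino acid stress genes were 6 higher and 13 lower of 20 (camera adjusted p = 0.0346, and adjusted p = 0.102 with an estimated correlation). Growth arrest genes and cell cycle inhibitors were 3 higher and 10 lower of 21 (camera adjusted p = 0.0126, and adjusted p = 0.124 with an estimated correlation), with Gadd45a 3.69-fold lower. Wnt, Notch and BMP targets were 2 higher and 7 lower of 14 (camera adjusted p = 0.0478, and adjusted p = 0.102 with an estimated correlation), with Id2 3.62-fold lower. Pluripotency genes were 6 higher and 8 lower of 17 (camera adjusted p = 0.0538), with Klf4 3.65-fold lower at 144 ± 5.79 CPM. Lin28a was at 260 ± 5.49 CPM in GS_diff1.

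The remaining lists did not pass in GS_diff1 against GS. Cardiac mesoderm and progenitor genes were 5 higher and 10 lower of 22 (camera adjusted p = 0.101), with Fgf10 4.15-fold lower. Endothelial genes were 8 higher and 7 lower of 19 (camera adjusted p = 0.945), with the endothelial transcription factor Erg 4.02-fold higher at 6.07 ± 0.263 CPM. Epithelial and mesothelial genes were 8 higher and 8 lower of 24 (camera adjusted p = 0.189), with Krt8 5.77-fold and Krt18 4.51-fold higher. Endoderm and hepatocyte genes were 2 higher and 2 lower of 8 (camera adjusted p = 0.945). Neural and glial genes were 1 higher and 3 lower of 11 (camera adjusted p = 0.677), and leukocyte genes were 3 higher and 4 lower of 13 (camera adjusted p = 0.835). The median, the mean and the test differed in sign for the fatty acid, endothelial, epithelial and endoderm lists.

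GS_diff2 was compared with GS to see what differed in cells placed in CMM medium with EGM2 solution. Cell cycle, cholesterol and glycolysis genes were mostly higher, and pluripotency, contractile and stress genes mostly lower. Adcyap1r1, the receptor of the neuropeptide PACAP (ENSRNOG00000012098, chromosome 4, 85662892 to 85711696), rose from 0 to 111.5 ± 3.69 CPM, at least 663-fold. Ace, the angiotensin converting enzyme of endothelium and other tissues, was at 90.3 ± 4.79 CPM against 0.315 ± 0.0364 in GS. The neuronal pentraxin gene Nptx1 was at 175 ± 4.76 CPM against 0.659 ± 0.293, and the imprinted growth factor Igf2 was 58.4-fold higher at 91.3 ± 1.65 CPM. The amino acid transporter gene Slc7a3 fell from 22.9 ± 1.48 to 0.301 ± 0.12 CPM and Mal2 from 18.9 ± 2.57 to 0.328 ± 0.0308. In all, 9651 of 14399 genes differed, 4797 higher and 4854 lower, and 3093 of them by at least 2-fold. With library totals only, 5456 were higher and 4156 lower.

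Cell cycle genes were 36 higher and 0 lower of 37 in GS_diff2 (camera adjusted p = 3.44e-31), with Tk1 6.31-fold, Birc5 6.30-fold and the centromere gene Cenpf 4.94-fold higher. Cholesterol synthesis genes were 23 higher and 0 lower of 24 (camera adjusted p = 2.14e-28), with Idi1 15.1-fold higher. Glycolysis and hypoxia genes were 20 higher and 1 lower of 25 (camera adjusted p = 2.27e-09), with the carbonic anhydrase Car9 3.72-fold and Ldha 2.67-fold higher. Fatty acid oxidation and oxidative metabolism genes were 16 higher and 8 lower of 30 (camera adjusted p = 0.509). Unfolded protein and amino acid stress genes were 6 higher and 12 lower of 20 (camera adjusted p = 0.000144). Chac1 was 30.2-fold, the pseudokinase gene Trib3 24.7-fold and the cystine transporter gene Slc7a11 12.5-fold lower. Immediate early genes were 5 higher and 14 lower of 21 (camera adjusted p = 1.92e-05), with Fos 5.79-fold lower.

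Pluripotency genes were 0 higher and 13 lower of 17 in GS_diff2 (camera adjusted p = 4.34e-07). Alpl, the tissue-nonspecific alkaline phosphatase, was 7.66-fold lower, and Lin28a was at 35.2 ± 2.61 CPM. Contractile genes were 5 higher and 12 lower of 19 (camera adjusted p = 0.000814, and adjusted p = 0.0486 with an estimated correlation). Myl9 was 9.17-fold, Acta2 8.93-fold and Ctgf 5.06-fold lower. Fibroblast and extracellular matrix genes were 13 higher and 15 lower of 31 (camera adjusted p = 0.268), with Eln 11.7-fold and Timp3 7.92-fold lower. Mgp stood at 1981 ± 36.9 CPM in GS_diff2 against 663 ± 21.1 in GS. Endothelial genes were 10 higher and 4 lower of 19 (camera adjusted p = 0.837). Esm1, a proteoglycan secreted by endothelial cells, was 4.18-fold higher at 160 ± 6.85 CPM, and Flt4, a receptor of vascular endothelial growth factors, was at 1.29 ± 0.422 CPM against 0.418 ± 0.195. Flt4 was at 3.58 ± 0.626 CPM in RCF. The transcription factor genes Sox17, Sox7 and Erg of the same list went the other way. Sox17 fell from 710 ± 12.9 to 282 ± 11 CPM, Sox7 from 66.3 ± 3.68 to 22.7 ± 0.921 and Erg from 1.515 ± 0.282 to 0.322 ± 0.0992. Pericyte genes were 4 higher and 3 lower of 8 (camera adjusted p = 0.837), with Kcnj8 8.21-fold and Abcc9 3.82-fold higher. Kcnj8, at 15.4 ± 2.42 CPM, was near its RCF level of 15.1 ± 0.642. Abcc9, at 73.4 ± 4.13 CPM, was above its RCF level of 11.9 ± 0.409. Both genes lie close together on chromosome 4 (176782498 to 176789304 and 176805431 to 176922424). Cardiomyocyte genes were 9 higher and 7 lower of 23 (camera adjusted p = 0.346), with Tnni1 at 15.2 ± 2.64 CPM against 0.536 ± 0.133. Hcn4 of the same list was at 0.208 ± 0.188 CPM against 9.61 ± 0.314 in GS.

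The other lists did not pass in GS_diff2 against GS. Cardiac mesoderm and progenitor genes were 4 higher and 12 lower of 22 (camera adjusted p = 0.301), with Myocd, a coactivator of muscle genes, 3.68-fold lower. Epithelial and mesothelial genes were 6 higher and 14 lower of 24 (camera adjusted p = 0.231), with the mesothelial factor Wt1 3.44-fold lower and Lrrn4 at 0.183 ± 0.0443 CPM against 4.56 ± 0.811. Endoderm and hepatocyte genes were 2 higher and 5 lower of 8 (camera adjusted p = 0.156), with Sox17 2.52-fold lower. Neural and glial genes were 1 higher and 4 lower of 11 (camera adjusted p = 0.156), and leukocyte genes were 4 higher and 3 lower of 13 (camera adjusted p = 0.973). Interferon response genes were 10 higher and 8 lower of 26 (camera adjusted p = 0.973), with the chemokine gene Cxcl10 2.98-fold higher. Growth arrest genes and cell cycle inhibitors were 8 higher and 11 lower of 21 (camera adjusted p = 0.346), with Sesn2 6.41-fold lower. Wnt, Notch and BMP targets were 4 higher and 8 lower of 14 (camera adjusted p = 0.129), with the Wnt feedback gene Nkd1 5.23-fold lower. Adjusted over the list alone, 29 matrix, 15 endothelial, 20 growth arrest and 22 glycolysis genes were called instead of 28, 14, 19 and 21, and the other 16 counts were equal. The median, the mean and the tests differed in sign for the interferon, leukocyte and pericyte lists.

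GS_diff2 and GS_diff1 were compared directly, which tests what differed between both differentiated groups. Most contractile genes were lower in GS_diff2, and the pericyte channel genes Abcc9 and Kcnj8 were higher. Acta2 was 97.1-fold lower in GS_diff2, at 9.85 ± 1.3 against 961 ± 13.7 CPM (log2 -6.60 ± 0.0569, adjusted p = 1.34e-30). Abcc9 was higher, at 73.4 ± 4.13 against 0.604 ± 0.287 CPM. Adcyap1r1 was at least 715-fold higher and Ace was at 90.3 ± 4.79 against 0.255 ± 0.116 CPM. Car3 fell to 0 in GS_diff2, at least 202-fold lower, and the actin-binding gene Limch1 was at 0.417 ± 0.154 against 46.5 ± 0.359 CPM. In all, 9167 of 14399 genes differed, 4628 higher and 4539 lower in GS_diff2, and 2735 of them by at least 2-fold.

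Contractile genes were 3 higher and 15 lower of 19 in GS_diff2 (camera adjusted p = 6.36e-11), with Myl9 18.6-fold and Tagln 8.92-fold lower. Pericyte genes were 6 higher and 2 lower of 8 (camera adjusted p = 0.018, and adjusted p = 0.143 with an estimated correlation), with Kcnj8 at 15.4 ± 2.42 CPM against 0.158 ± 0.095. Fibroblast and extracellular matrix genes were 17 higher and 11 lower of 31 (camera adjusted p = 0.237). Mgp (ENSRNOG00000005695, chromosome 4, 170856751 to 170860225) was 44.8-fold, Lum 5.84-fold and Col6a2 3.33-fold higher. Epithelial and mesothelial genes were 5 higher and 15 lower of 24 (camera adjusted p = 0.00276), with Cldn4 6.43-fold lower. Pluripotency genes were 3 higher and 9 lower of 17 (camera adjusted p = 0.018, and adjusted p = 0.119 with an estimated correlation), with the DNA methyltransferase Dnmt3b 7.50-fold and Lin28a 7.39-fold lower. Cardiomyocyte genes were 7 higher and 12 lower of 23 (camera adjusted p = 0.479), with phospholamban (Pln) at 0.678 ± 0.152 CPM against 4.84 ± 0.795. Cardiac mesoderm and progenitor genes were 9 higher and 9 lower of 22 (camera adjusted p = 0.927), with Hopx 29.5-fold and Bmp2 9.40-fold higher and Myocd 10.3-fold lower. Endothelial genes were 7 higher and 7 lower of 19 (camera adjusted p = 0.94), with Esm1 7.24-fold higher and Erg at 0.322 ± 0.0992 CPM against 6.07 ± 0.263.

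**Figure D3:**
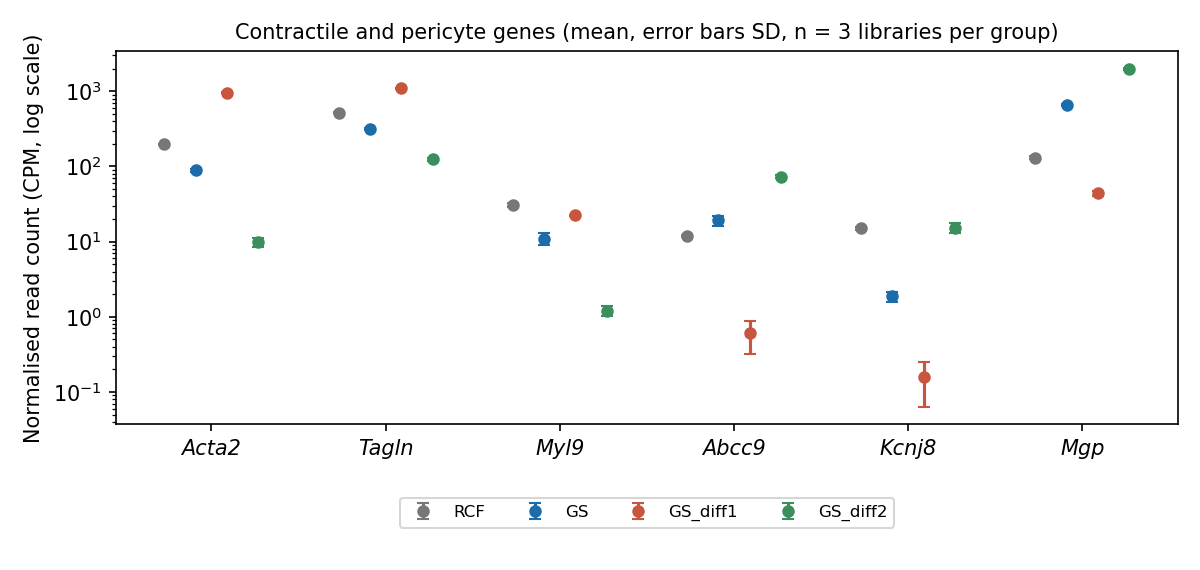
Normalised read counts (CPM, log scale on the vertical axis) of Acta2, Tagln, Myl9, Abcc9, Kcnj8 and Mgp in the 4 groups, as mean (point) and SD (error bar, n = 3). Acta2 stood at 961 CPM in GS_diff1 and 9.85 in GS_diff2, while Abcc9 stood at 0.604 and 73.4.

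Interferon response genes were 23 higher and 2 lower of 26 in GS_diff2 against GS_diff1 (camera adjusted p = 1.34e-05), with Cxcl10 7.19-fold and Oasl 6.11-fold higher. Cholesterol synthesis genes were 22 higher and 1 lower of 24 (camera adjusted p = 1.82e-10), with Msmo1 3.62-fold higher. Glycolysis and hypoxia genes were 21 higher and 2 lower of 25 (camera adjusted p = 7.06e-06), with adrenomedullin (Adm) 5.05-fold higher. Unfolded protein and amino acid stress genes were 6 higher and 12 lower of 20 (camera adjusted p = 0.000163), with Slc7a11 13.7-fold and Chac1 11.4-fold lower. Cell cycle genes were 20 higher and 7 lower of 37 (camera adjusted p = 0.0399, and adjusted p = 0.119 with an estimated correlation), with Gins2 2.45-fold higher. Growth arrest genes and cell cycle inhibitors were 9 higher and 7 lower of 21 (camera adjusted p = 0.545), with Cdkn2a 4.76-fold and its neighbour Cdkn2b 3.44-fold higher. Immediate early genes were 10 higher and 6 lower of 21 (camera adjusted p = 0.226), with Fosl1 8.002-fold higher. Wnt, Notch and BMP targets were 4 higher and 7 lower of 14 (camera adjusted p = 0.927), with camera pointing down and fry up. Fatty acid oxidation genes were 13 higher and 9 lower of 30 (camera adjusted p = 0.777), and endoderm genes were 2 higher and 5 lower of 8 (camera adjusted p = 0.101). Neural and glial genes were 2 higher and 5 lower of 11 (camera adjusted p = 0.356), and leukocyte genes were 3 higher and 1 lower of 13 (camera adjusted p = 0.839). Adjusted over the list alone, 20 cardiomyocyte, 28 cell cycle and 26 interferon genes were called instead of 19, 27 and 25, and the other 17 counts were equal.

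Both differentiated groups were also set against the parental fibroblasts, as counts and lists only. GS_diff1 differed from RCF in 10858 genes, 5476 higher and 5382 lower, and GS_diff2 in 10435 genes, 5336 higher and 5099 lower. Cell cycle genes were higher in 35 of 37 members in GS_diff1 (camera adjusted p = 2.43e-20) and 36 of 37 in GS_diff2 (9.28e-28), with 0 lower in either. Cholesterol synthesis genes were 13 higher and 7 lower of 24 in GS_diff1 (camera adjusted p = 0.535) and 21 higher and 0 lower in GS_diff2 (3.02e-08). Interferon response genes were 1 higher and 24 lower of 26 in GS_diff1 (camera adjusted p = 4.33e-06), and 6 higher and 12 lower in GS_diff2 (0.0765). Cardiomyocyte genes were 14 higher and 6 lower of 23 in GS_diff1 (camera adjusted p = 0.0438, and adjusted p = 0.0748 with an estimated correlation). They were 12 higher and 3 lower in GS_diff2 (camera adjusted p = 0.018, and adjusted p = 0.0527 with an estimated correlation). Endothelial genes were 12 higher and 4 lower of 19 in GS_diff1 (camera adjusted p = 0.0786). They were 11 higher and 4 lower in GS_diff2 (camera adjusted p = 0.0162, and adjusted p = 0.0527 with an estimated correlation). Leukocyte genes were 0 higher and 12 lower of 13 in GS_diff1 (camera adjusted p = 0.00578, and adjusted p = 0.0517 with an estimated correlation). They were 1 higher and 10 lower in GS_diff2 (camera adjusted p = 0.00679, and adjusted p = 0.0527 with an estimated correlation).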

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

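Comparing directions in GS_diff1 and GS_diff2, with its simulation, was chosen after the comparisons with GS had been seen. The genes below moved at least 2-fold in opposite directions in GS_diff1 and GS_diff2 against GS, so that by construction they differ at least 4-fold between both groups, and the direct test adds only the size. Such genes are a minority: 173 genes moved at least 2-fold in opposite directions and 1225 in the same direction (673 higher and 552 lower in both). Independent lists of these sizes would share 282 in opposite directions and 280 in the same direction (137 and 143), and 10 simulations of unchanged groups against the same controls gave 0 of either. Those simulations hold no changed genes, so they cannot show what shared controls do to genes that did change. Both comparisons use the same 3 GS libraries, too few to split into separate controls of 2 each, so part of the excess in the same direction can come from them. Values below are fitted log2 fold changes of GS_diff2 against GS_diff1, with n = 3 libraries per group.

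Contractile and cardiac muscle genes higher in GS_diff1 and lower in GS_diff2 were Acta2 (-6.60), Myl9 (-4.22), Tagln (-3.16), the coactivator gene Myocd (-3.37), Pln (-2.83) and Actn2 (-3.65). Actn2 had only a few counts in GS_diff2 (0.105 ± 0.139 CPM, against 1.48 ± 0.0232), so its size is poorly set. Actn2, GS_diff2 versus GS_diff1, was -5.52 without GS_diff2 replicate 2. The contractile list as a whole rose in GS_diff1 and fell in GS_diff2 against GS (camera adjusted p = 0.0277 and 0.0486 with an estimated correlation). It differed directly (camera adjusted p = 6.36e-11, and adjusted p = 0.00381 with an estimated correlation). Limch1 (-6.81) and Nrep (-5.33) went the same way, as did Erg (-4.20), Fgf8 (-2.47) and Dnmt3b (-2.91). Fgf8 was no longer called in GS_diff2 against GS without GS replicate 1 (log2 -1.10).

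Tdh (-5.31) and the Wnt target Lgr5 (-6.36) were higher in GS_diff1 (8.09 ± 0.576 and 4.52 ± 0.574 CPM) and near 0 in GS_diff2 (0.206 ± 0.161 and 0.0492 ± 0.0521 CPM), so their sizes are poorly set. Tdh, GS_diff2 versus GS_diff1, was -6.00 without GS_diff2 replicate 3, and Lgr5, GS_diff2 versus GS_diff1, was -7.24 without GS_diff2 replicate 1. Car3 (-12.21) and the retinoic acid enzyme gene Aldh1a2 (-9.50) had 0 counts in GS_diff2. Those fitted values are no bounds, and the bounds are at least 202-fold and 30.7-fold lower.

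Higher in GS_diff2 and lower in GS_diff1 were the pericyte channel genes Abcc9 (6.95) and Kcnj8 (6.58), the matrix gene Mgp (5.49), Hopx (4.88), the chemokine gene Cxcl10 (2.85) and the receptor gene Flt4 (2.84). Kcnj8 was at 0.158 ± 0.095 CPM in GS_diff1, near the floor of 3 counts, and 15.4 ± 2.42 in GS_diff2, and Flt4 at 0.179 ± 0.1 and 1.29 ± 0.422, so their sizes are poorly set. The same holds for Nptx1 (10.89), at 0.0897 ± 0.0871 and 175 ± 4.76 CPM, and Aldh3a1 (9.40), at 0.0697 ± 0.0763 and 50.8 ± 1.89. Nptx1, GS_diff2 versus GS_diff1, was 11.63 without GS_diff1 replicate 3. Aldh3a1, GS_diff2 versus GS_diff1, was 8.80 without GS_diff1 replicate 1 and 10.61 without GS_diff1 replicate 2. Cd36 (7.60) had 0 counts in GS_diff1, and its bound is at least 7.82-fold higher. No explanation for these differences was tested.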

How the results depend on the processing

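The counts over other splits were chosen after the comparisons had been seen, and the alternatives were set before the data were examined.

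Under the 8 other settings of the fit, the number of changed genes was 9521 to 10678 for GS against RCF (10262 reported), 8805 to 9320 for GS_diff1 against GS (9256), 9094 to 9819 for GS_diff2 against GS (9651) and 8749 to 9331 for GS_diff2 against GS_diff1 (9167). It was 10091 to 11320 for GS_diff1 against RCF (10858) and 9682 to 10883 for GS_diff2 against RCF (10435). Leaving out single libraries gave 9839 to 10049, 8715 to 8850, 9112 to 9315, 8631 to 8775, 10502 to 10632 and 10022 to 10100, in the same order. With the replicate number as a block, the counts were 10166, 9135, 9538, 9054, 10767 and 10365. The numbers do not pair the libraries: 5 of 12 libraries correlated best with their own number, and same-number correlations were -0.045 to 0.076. Library totals alone turned the balance to 4383 higher and 6024 lower in GS against RCF, 5100 and 4165 in GS_diff1 against GS, 5456 and 4156 in GS_diff2 against GS, and 4803 and 4347 in GS_diff2 against GS_diff1. The median of all genes shifted by -0.099, 0.062, 0.085 and 0.023 on the log2 scale. In GS_diff1 and GS_diff2 against RCF the balance was 5263 and 5618, and 5231 and 5209. Each real split gave the largest count, 1 of 10 splits, and the highest other count was 0 for GS_diff2 against GS and the 3 comparisons with RCF, and 1 for the remaining comparisons. These splits are too few for a share under 0.05. Every other split also puts libraries of both groups under each label, which widens the spread within a label. A low count there was thus fixed in advance and is no support for the real split.

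For named genes, 2266 values kept direction and side of the threshold under other settings, 3 gained a call and 1 lost it. With single libraries left out, 1706 did, 2 gained a call and 8 lost it. The gains were those of Tert given in the report. The losses were Sall4 and Tert as given there, and without GS replicate 1 Rb1 (log2 -0.22) and Tie1 (1.02) in GS_diff1 and Fgf8 (-1.10) in GS_diff2 against GS. Elavl3 in GS_diff2 against GS_diff1 lost its call in 3 of these fits (-1.01, -1.03 and -0.83). Fewer libraries per group leave less power, and for the other settings the cause was not tested.

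For gene lists, 191 results were the same under other tests or a block, 33 gained a call, 12 lost it and 4 reversed. With an estimated correlation, calls ended for leukocyte (0.0599) and fatty acid genes (0.124) in GS against RCF. They ended for growth arrest (0.124), glycolysis (0.151), unfolded protein (0.102) and Wnt (0.102) genes in GS_diff1 against GS, and pluripotency (0.119), pericyte (0.143) and cell cycle (0.119) genes in GS_diff2 against GS_diff1. With a replicate block, glycolysis (0.0653), unfolded protein (0.0666) and Wnt (0.1) genes lost theirs in GS_diff1 against GS, and for neither setting was the cause tested.

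Fry does not compare a list with other genes, and called more lists. It reversed contractile (0.000461) and glycolysis (0.00431) genes in GS against RCF, pericyte genes (5.58e-07) in GS_diff2 against GS and Wnt targets (0.000922) in GS_diff2 against GS_diff1, and the cause was not tested. Gains in GS against RCF were cardiomyocyte (4.16e-09), endothelial (1.23e-11), neural (4.78e-06), pericyte (5.02e-09), cell cycle (3.32e-07) and interferon (6.05e-07). Gains in GS_diff1 against GS were cardiomyocyte (2.77e-08), cardiac mesoderm (7.28e-08), pluripotency (2.72e-08), endothelial (3.03e-05), epithelial (8.66e-09), endoderm (0.000347), neural (0.00137) and leukocyte (0.0279). Gains in GS_diff2 against GS were fibroblast (2.23e-10), cardiomyocyte (1.46e-07), cardiac mesoderm (3.7e-06), endothelial (0.0336), epithelial (7.62e-06), endoderm (3.66e-09), neural (1.46e-07), growth arrest (4.73e-07), fatty acid (0.0141) and Wnt (1.62e-07). Gains in GS_diff2 against GS_diff1 were fibroblast (2.86e-09), cardiomyocyte (0.00288), cardiac mesoderm (7.4e-05), endothelial (3.39e-05), endoderm (2.27e-08), neural (7.02e-07), leukocyte (0.00547), growth arrest (0.000324) and immediate early (5.14e-07).

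At this depth, 3 counts correspond to 0.127 to 0.193 CPM, so folds of genes near 0 counts in a group are poorly set.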

Other observations

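The counts of genes absent from one group and the tests on mitochondrial and imprinted genes were chosen after their values had been seen, the chromosome 15 tests followed a look at the medians of whole chromosomes, and the requirement that each part exceed its matched lists was added after its value was seen.

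Among tested genes, 29 had 0 counts in every RCF library and at least 10 CPM in GS. They include the epithelial genes Krt18 (161 CPM), Cldn6 (79.3), Esrp1 (67.6), Lad1 (63.5), Pkp3 (18.03) and the epithelial transcription factor gene Elf3 (15.4). The other way there were 2 genes, C7 (53.8 CPM) and Adgre1 (14.3), and no gene met the rule for GS_diff1 or GS_diff2 at 0 against GS. No test for epithelial genes was run on the 29, and Lad1, Pkp3 and Elf3 were picked after their values were seen.

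Genes of chromosome 15, which carries Gata4 and Rb1, were higher in GS than in RCF as a group, with a median log2 difference of 0.219 to the other autosomes over 389 genes, and the next chromosome was 17 at 0.117. Expression level and gene length as the whole cause are argued against by 10000 matched lists, whose central range was -0.08 to 0.091 (percentile 100). The lists draw genes singly and make no allowance for neighbouring genes that change together. Chromosome 17 at 0.117 also lies above that range, so the percentile does not show how unusual chromosome 15 is. A few strongly changed genes are argued against by the share above the autosomal median, 61.4% against 46.6% to 55.2% on other autosomes. This share follows the median by which the chromosome was picked, so it is no separate support for the difference itself. An extra copy in part of the cells may also play a part and stays open: by position, the 3 parts gave 0.263, 0.113 and 0.242, and although each met the bound of 0.1 set beforehand, the middle one lies inside its matched range (-0.145 to 0.152). Per library relative to RCF, the difference was 0.229 ± 0.017 in GS, 0.347 ± 0.013 in GS_diff1 and 0.106 ± 0.014 in GS_diff2, and no DNA was measured here. By fitted changes against RCF, chromosome 15 was at 0.34 in GS_diff1, with chromosome 17 next at 0.086. In GS_diff2 it did not stand out, at 0.074 against 0.12 for chromosome 20 and -0.125 for chromosome 18.

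All 13 mitochondrial protein-coding genes were lower in GS than in RCF (camera adjusted p = 1.5e-20, and adjusted p = 0.0467 with an estimated correlation), with Mt-co1 at 1029 ± 20.6 CPM against 1.13e4 and Mt-cytb at 166 against 2405. A fall of mitochondrial content that lowers all of them exactly alike is argued against by their log2 changes. These span 2.632, from -4.05 to -1.42, with a largest standard error of 0.25. The 13 changes also spread in GS_diff1 (-0.769 to 0.566) and GS_diff2 (-0.587 to 1.034) against RCF. A lower content with such a spread on top of it is therefore not tested by the span. Scaling is argued against by a median of -3.016 with library totals only, and a matching fall of the nuclear respiratory chain genes by their median of -0.127 (13 higher, 33 lower of 70, camera adjusted p = 0.0988). What lowered these transcripts stays open.

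Leukocyte genes were lower in GS than in RCF, and a candidate explanation is leukocytes among the primary fibroblasts that were lost from the GS cells. In a second list of leukocyte genes, none of them in the other lists, 77.8% of 27 tested genes were lower in GS (21 lower, 5 higher, camera adjusted p = 0.0287, and adjusted p = 0.13 with an estimated correlation), 81.5% in GS_diff1 and 74.1% in GS_diff2 against RCF. The bar of at least 75% in all 3 groups was thus missed in GS_diff2, and the explanation stays open. The most abundant genes were Cyba, at 134.3 CPM in RCF and 73.0 in GS, and Cd48, at 54.99 and 34.99, while Cybb was at 10.97 and 0.0732. In the list, 21 genes reached 1 CPM in RCF and 7 in GS, so GS cells express some of them too.

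Of 15 tested imprinted growth genes, 10 were higher and 5 lower in GS against RCF (camera adjusted p = 0.0287, from 0.00956 before adjustment over 24 tests, and adjusted p = 0.0976 with an estimated correlation). The list was made after Cdkn1c and Mir675 had been seen to rise and holds both, so the test restates what was seen and a rise of the set stays open. Plagl1 was 20.4-fold, Peg3 6.02-fold and Grb10 4.45-fold higher, while Ndn was 5.73-fold, Mest 2.57-fold and Igf2r 2.29-fold lower. Allele-specific expression was not analysed here.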
